A study of Mus musculus with 2 samples.

How the data were processed

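The series held 2 hybridisations of 1 p400 ChIP against 1 input from mouse embryonic stem cells, 1 on each array of a promoter set with different probes. Per the labels' protocols, 1 mg of extract was used for the immunoprecipitation, and 4 ng of immunoprecipitated DNA and 4 ng of input DNA were amplified with a BioPrime kit before labelling. Such amplification can change the relative abundance of fragments, and its effect was not measured here. Each array was its own group with n = 1, so no test between samples was made. The number of arrays limits the precision.

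The deposited scanner files gave 1 signal intensity per probe for each dye, extracted with NimbleScan 2.3.31 per the file headers. Whether a background was subtracted is not given in the sources used here. Per the labels, Cy5 was the immunoprecipitate and Cy3 the input, and the dyes were not swapped, so a dye bias stays in every ratio. The authors' processed values were log2 ratios in the series' value table. The submitters' processing notes name limma and mm8 but not the fit. Set against the scanner values of the same probes, they ran in the direction of immunoprecipitate over input on a log2 scale, with r = 0.976 on array 1 and 0.977 on array 2. Their medians were 0.08 and 0.09 for promoter probes and −0.01 and 0.00 for random probes. They departed from the raw ratio by an amount that changed with brightness, and the normalisation behind it stays unknown. They were used as an alternative.

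For each probe log2(Cy5/Cy3) was computed from the signals as given, and the median over the promoter probes of the array was subtracted, without loess or quantile normalisation. This median was −0.87 on array 1 and −0.02 on array 2 before centring. The random probes then lay at −0.47 and 0.13, so centring on them in place of the promoter probes moves every value by that much. The ratio rose with the mean log2 signal on array 1 (r = 0.508 across probes) and hardly on array 2 (r = 0.0812), which bears on the comparison of dim with bright regions. The immunoprecipitate signal lay above the 95th percentile of the random probes for 69.3% of promoter probes on array 1 and 52.0% on array 2, and the input signal for 63.8% and 42.0%.

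A window was 5 successive probes of a region spanning at most 800 bp. The peak of a region was its highest window mean and its trough the lowest. Of 21632 tiled regions, 37 with fewer than 10 probes were left out. The threshold of an array was the smallest multiple of 0.05 at which regions with a trough at or below its negative numbered at most 5% of those with a peak at or above it. The lower tail stands for noise within an array, assumes that noise is symmetric about the array's median, and does not measure variation between cultures. Shares have 95% Wilson intervals. Differences of shares have 95% normal intervals from the binomial variances, and SEs of profiles are over regions. All of these treat regions as independent. Calls clustered along chromosomes and the peaks of neighbouring regions were correlated, so the intervals are likely too narrow.

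The named regions were, by a rule fixed before the data were examined, the 8 on each array with the highest peak among those whose 5 probes all lay above the array median. Gene lists, a comparison with promoter CpG content and distances to annotated starts were also planned then. They were not run. The files name regions by mm8 coordinates alone, a genome or gene annotation of mm8 was not used here, and coordinates were not converted between assemblies. The gene table of GRCm38.p6 served only to count rows of neighbouring olfactory and vomeronasal receptor genes per chromosome, for which gene order but no position was taken. The profile was therefore taken along the tiled region. All columns of the authors' value tables were mapped to their sample by name.

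The procedure was tested on simulated arrays with the noise and neighbour correlation of the uncalled regions. In 50 regions of each size a bump of known height was added, flat around a random centre and falling to 0 on both sides. The shares recovered hold for a bump of that width. At the thresholds of the real arrays, regions raised by a log2 of 1 were recovered in 74% of cases on array 1 and 46% on array 2. At 1.5 the shares were 94% and 88%, at 2 they were 96% on both, and at 3 they were 100% and 96%. Of the 10789 and 10806 simulated regions, 348 and 265 were called, 166 and 102 of them without having been raised. The rule itself set higher thresholds on the simulated arrays, 1.20 and 1.25. At these, 24% and 26% were recovered at a log2 of 1 and 88% and 78% at 1.5, with 5 and 4 calls of regions not raised. Far fewer regions were raised than were called on the real arrays. Simulated noise was centred on 0. In uncalled regions of exactly 4000 bp the mean ratio was about −0.28 to −0.23 on array 1 and −0.19 to −0.17 on array 2. A rise of the same size would peak lower in such regions, so the shares recovered are likely too high for the real arrays. The noise came from regions picked for having no call, so calls of regions not raised may be understated.

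Alternatives were normexp background correction with an offset of 50, loess within the array with a span of 0.3, the authors' processed values, and Tukey biweight centring. Others left out the 10% of probes with the lowest input signal or probes at or above 60000 in either dye. Windows of 3 or 7 probes, the median in the window, at least 20 probes per region, a mirrored share of at most 1%, a fixed threshold of 1 and bins of 100 bp were also tried. Background correction and loess used limma 3.58.1 in R 4.3.3. The rest used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.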

Results

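p400 is the large ATPase subunit of the Tip60-p400 complex, which acetylates histones and exchanges histone variants in chromatin. Its position on promoters was measured in mouse embryonic stem cells, the self-renewing cells of the early embryo kept in culture. Chromatin from 1 cross-linked 10 cm dish was immunoprecipitated with an antibody to p400. The recovered DNA and input DNA were amplified and hybridised together to a pair of promoter tiling arrays, with the immunoprecipitate in Cy5 and the input in Cy3. The arrays held different promoters. Array 1 covered chromosomes 1 to 8 and part of chromosome 9, and array 2 covered the rest of chromosome 9, chromosomes 10 to 19, X, Y and unplaced sequence. The design thus held 1 immunoprecipitate and 1 input with no replicates, and a ChIP with a control antibody was not analysed here. Differences below carry no p-value between samples, and intervals cover counting error only, as if regions were independent.

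Each array carried 389307 probes, of which 385301 on array 1 and 385507 on array 2 lay in tiled promoter regions and the others were random-sequence controls. The tiled regions numbered 10807 and 10825, with a median of 34 probes per region on both arrays. The median signal of the promoter probes over that of the random probes was 3.21-fold for the immunoprecipitate and 2.02-fold for the input on array 1. On array 2 the values were 2.56-fold and 2.63-fold. Regions are given by their coordinates on mm8, as the array design names them.

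The first question was which promoters p400 occupied. DNA of the p400 ChIP was enriched over input at a large share of them. Without a control ChIP, binding of p400 cannot be told apart from nonspecific precipitation here, so the calls may include both. Of 21595 regions with at least 10 probes, 8175 (37.9%) held a stretch of 5 probes above the threshold of their array. On array 1 these were 4689 of 10789 regions (43.5%, 95% Wilson interval 42.5 to 44.4), and on array 2 they were 3486 of 10806 (32.3%, 31.4 to 33.1). The median peak of the called regions was 3.23-fold over input on array 1 and 3.02-fold on array 2. A peak of at least 4-fold (log2 of 2) was reached by 1713 regions (15.9%) on array 1 and 1004 (9.29%) on array 2, while 0 regions on either array fell to the mirrored value of −2. Called stretches that ended inside the tiled region had a median width of 1100 bp on array 1 (2460 regions) and 1000 bp on array 2 (1996 regions). These widths run from the first to the last probe of the 5-probe windows above the threshold, so they cannot be narrower than a window. The other called stretches, 47.5% on array 1 and 42.7% on array 2, lay at an edge of their region.

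The threshold was a log2 ratio of 0.90 on array 1 and 1.00 on array 2, where depletion of the same size was found in 204 and 150 regions, 4.35% and 4.30% of the number called. The gap between the arrays was not kept under the authors' processed values, with which 4490 regions (41.6% of those tested) were called on array 1 and 4601 (42.6%) on array 2. Nor was it kept with normexp (37.1% and 36.5%) or with loess (33.8% and 36.6%). Centring on the random control probes, for which the same rule set the thresholds anew at 0.40 and 1.15, gave 8698 calls on array 1 and 2580 on array 2.

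**Figure D1:**
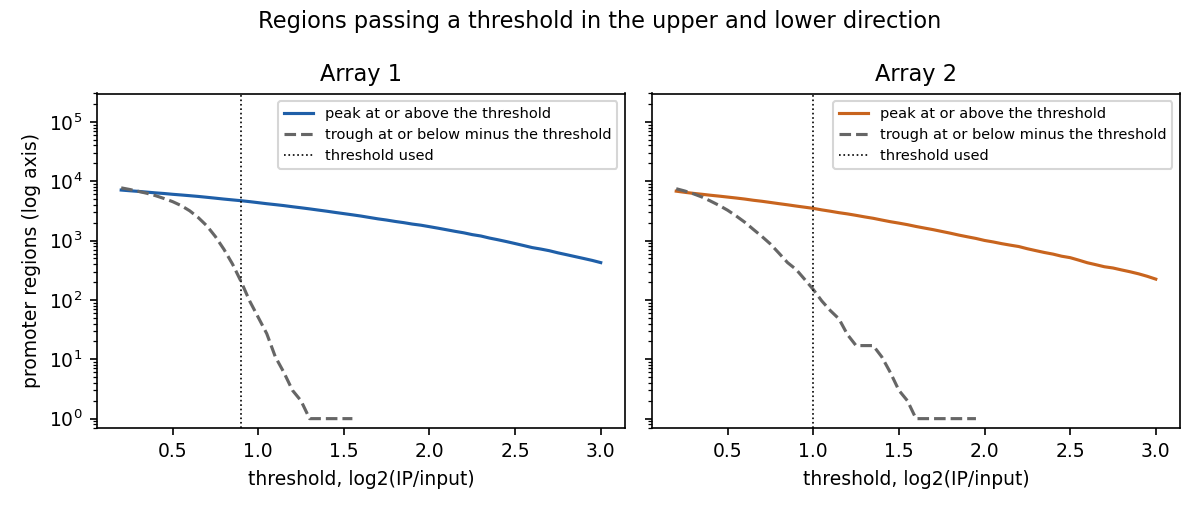
Number of promoter regions (log axis) whose highest 5-probe mean lay at or above a log2(IP/input) threshold (solid), and whose lowest lay at or below its negative (dashed), for array 1 (left) and array 2 (right). At the thresholds used (dotted, 0.90 and 1.00) 4689 and 3486 regions had a peak and 204 and 150 a trough of that size.

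The strongest peaks of the p400 ChIP had log2 ratios of 4.31 to 5.61 by the mean of 5 neighbouring probes, on chromosomes spread over the genome. The highest on array 1, by all probes, was in the region chr4:46409770-46413787, with a log2 ratio of 5.61 ± 0.36 (SD of the 5 probes). It was followed by chr5:22943014-22948993 at 5.31 ± 0.42, chr6:117869184-117877074 at 5.22 ± 0.28, chr8:109779529-109790724 at 5.12 ± 0.21 and chr9:15051141-15058868 at 5.05 ± 0.22. The next were chr7:3303874-3307887 at 4.90 ± 0.39, chr4:128688917-128695213 at 4.81 ± 0.75 and chr7:78766189-78770320 at 4.78 ± 0.21. On array 2 the highest was chr18:35079547-35083575, with a log2 ratio of 4.98 ± 0.06, or 31.5-fold. Behind it came chr13:49690829-49694830 at 4.73 ± 0.41, chr19:46122059-46130073 at 4.50 ± 0.39 and chr15:43112021-43116021 at 4.47 ± 0.44. The remaining peaks were chr19:9030992-9036015 at 4.43 ± 0.27, chr9:63968130-63978063 at 4.42 ± 0.23, chr18:46719784-46726102 at 4.34 ± 0.25 and chr9:59451363-59455384 at 4.31 ± 0.43. The order of neighbours in these lists often rested on less than the spread of the 5 probes, and in 7 of the 16 windows 1 to 4 probes had an immunoprecipitate signal in the saturated range (at least 60000). These were 4 on array 1 (chr4:46409770-46413787, chr5:22943014-22948993, chr6:117869184-117877074 and chr8:109779529-109790724) and 3 on array 2 (both on chromosome 19 and chr9:59451363-59455384). Saturation lowers such ratios by an unknown amount, so their ranks are not fixed. With dim probes left out chr5:22943014-22948993 was above the first, at 5.41 against 5.31, so which region of array 1 was highest was not settled. With normexp the first came to 6.55, chr4:128688917-128695213 to 5.43 and chr9:63968130-63978063 to 5.09, and with windows of 7 probes chr18:35079547-35083575 came to 4.30. Gene names were not assigned, because the regions were named by mm8 coordinates and the gene table used here was built on another assembly.

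Enrichment differed with the tiled length of the region. The arrays tiled positions −3250 to 750 bp of each start, so a single start gives a region of exactly 4000 bp and starts a little apart on the same strand lengthen it by their distance. Among regions of exactly 4000 bp, 24.5% of 5104 were called on array 1 (23.3 to 25.6) and 15.6% of 4998 on array 2 (14.6 to 16.7). Among regions longer than that by at most 100 bp, 54.0% of 3094 (52.3 to 55.8) and 40.0% of 3115 (38.3 to 41.8) were called. The difference was 29.6 percentage points on array 1 (95% interval 27.5 to 31.7) and 24.4 points on array 2 (22.4 to 26.4). Over the alternatives it ranged from 17.6 to 30.4 points on array 1 and from 19.4 to 29.3 points on array 2. Both classes had nearly the same number of 5-probe windows, with medians of 29 and 28.

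Regions of 5500 to 6500 bp were called more often still, in 81.9% of 614 on array 1 (78.7 to 84.8) and 68.1% of 636 on array 2 (64.4 to 71.6). This length arises, among other ways, from starts less than 1000 bp apart that point away from each other, and from starts 1500 to 2500 bp apart on the same strand. Starts that point away from each other but lie several kb apart can also give it, and these lie near the edges. The difference from regions of exactly 4000 bp was 57.5 points on array 1 (54.2 to 60.7) and 52.5 points on array 2 (48.7 to 56.2). Longer regions hold more windows (medians of 47 and 46 against 29), but the median over regions of the mean of all probes rose as well. It was 0.55 against −0.22 on array 1 and 0.39 against −0.14 on array 2.

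**Figure D2:**
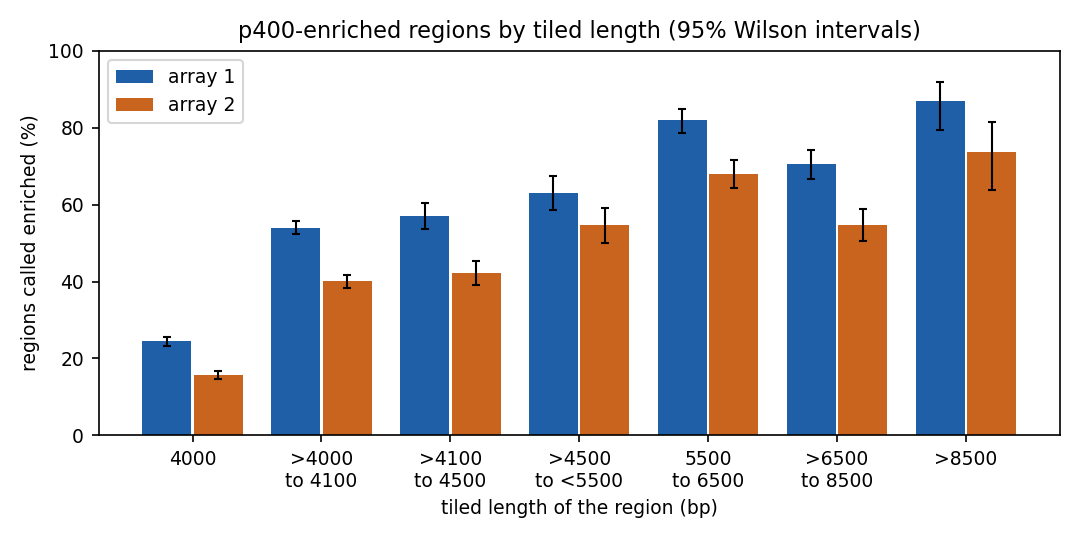
Percent of promoter regions called enriched in the p400 ChIP (vertical axis) by tiled length in bp (horizontal axis), for array 1 (blue) and array 2 (orange), with 95% Wilson intervals. Regions of exactly 4000 bp were lowest, at 24.5% and 15.6%, and those of 5500 to 6500 bp reached 81.9% and 68.1%.

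The second question was where p400 lay relative to the transcription start. In regions of 5500 to 6500 bp, a divergent pair of starts less than 1000 bp apart would lie near the middle. There the mean ratio was highest within 1000 bp of the middle. It exceeded that of probes at least 2500 bp away by a log2 ratio of 0.74 on array 1 (SE 0.03 over 614 regions) and 0.67 on array 2 (SE 0.03 over all but 1 of 636 regions). The difference was above 0 in 83.1% and 83.0% of these regions. Among the called ones, 75.9% on array 1 and 80.8% on array 2 had their peak within 1000 bp of the middle, where 38.8% and 39.0% of the windows were centred.

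On array 1, probes 500 to 750 bp from the middle exceeded those within 250 bp of it by 0.17 (SE 0.03, 606 regions), in 59.4% of regions. On array 2 the difference was 0.06 (SE 0.02, 631 regions), in 53.4%. The difference was not kept after normexp background correction, which gave −0.011 on array 1 and 0.022 on array 2 (95% interval ± 0.051), and came to 0.078 on array 1 after loess. The highest values among the alternatives came with bins of 100 bp, 0.29 on array 1 and 0.093 on array 2.

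**Figure D3:**
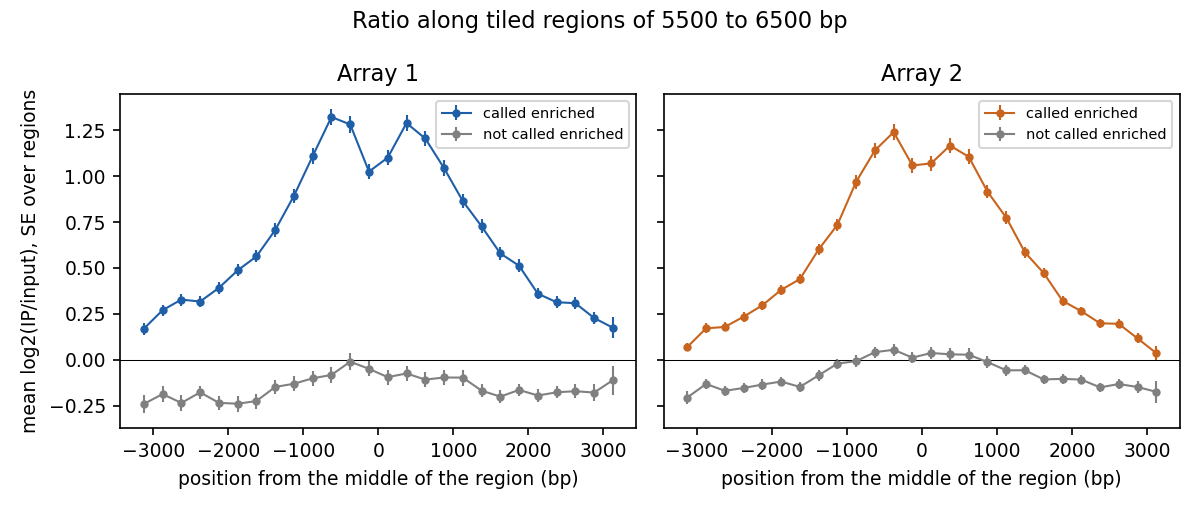
Mean log2(IP/input) in bins of 250 bp against position from the middle of the tiled region, for regions of 5500 to 6500 bp on array 1 (left) and array 2 (right). Coloured points are regions called enriched, grey points the others, and bars are the SE over regions. Called regions rise to a maximum within 1000 bp of the middle on both arrays.

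In regions of exactly 4000 bp the start lies 750 bp from one edge, but the strand was not used here, so distances were taken to the nearer edge. Peaks of called regions lay within 1000 bp of the nearer edge in 62.3% of 1248 on array 1 and 59.8% of 781 on array 2, where 43.7% of windows were centred on both arrays. That share of windows is not the share to be met by a maximum of overlapping windows without a link to the start. Enrichment cut off by the end of the tiling also peaks at an edge. Over all lengths, 47.5% of called stretches on array 1 and 42.7% on array 2 lay at an edge. The excess therefore does not by itself place p400 at the start. The mean ratio of called regions was 0.74 at 250 to 500 bp from the nearer edge and 0.52 at 750 to 1000 bp on array 1. On array 2 it was 0.69 and 0.53. The difference was 0.22 (SE 0.02) and 0.16 (SE 0.02). At 1000 to 1500 bp from that edge the ratio of called regions exceeded that at 750 to 1000 bp by 0.08 on both arrays (SE 0.02). Called regions were selected for their peaks. Over all regions of exactly 4000 bp the first difference was 0.09 on array 1 (SE 0.0062, 5072 regions) and 0.013 on array 2 (SE 0.0051, 4977 regions), and in those not called it was 0.048 (SE 0.0050) and −0.015 (SE 0.0043). The second was 0.014 and 0.018 over all regions (SE 0.0050 and 0.0041), and −0.0082 and 0.0063 in those not called (SE 0.0041 and 0.0034).

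Neighbouring probes gave similar ratios, though no replicate measured their precision. Across probes, which are not independent replicates, the ratios of probes within 150 bp of each other correlated with r = 0.773 on array 1 (330294 pairs) and r = 0.762 on array 2 (330652 pairs). In regions that were not called r was 0.485 and 0.578. Pairs drawn at random gave r near 0. No promoter probe was on both arrays. The 1646 random-sequence probes that both arrays held had ratios with a Pearson r of 0.00840 and a Spearman rho of −0.0104 between them, while their signals had a rho of 0.555 for the immunoprecipitate and 0.417 for the input. The Pearson r of the ratios depended on the processing, with 0.0954 after normexp and 0.20 both after loess and in the authors' processed values. The median SD of the 5 probes in a region's peak window was 0.36 on array 1 and 0.31 on array 2.

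Chromosomes differed in the share of promoters called. On array 1 the share was highest on chromosome 8, at 49.1% of 1013 regions (46.0 to 52.1), and lowest on chromosome 6, at 37.5% of 1204 (34.9 to 40.3). The difference was 11.5 points (7.40 to 15.6), and the median probe ratio differed by 0.19 (SD 0.02 over 1000 redraws of regions), or by 0.12 with loess. Among the autosomes of array 2, chromosome 11 was highest with 37.5% of 1628 regions (35.2 to 39.8) and chromosome 14 lowest with 29.0% of 835 (26.0 to 32.1). That difference was 8.49 points (4.61 to 12.4), with median ratios 0.09 apart (SD 0.02), or 0.15 apart with normexp. Over the alternatives, chromosome 8 minus 6 ranged from 8.51 to 12.6 points and chromosome 11 minus 14 from 5.37 to 9.60 points. With the decile of input signal matched, the differences were 10.7 points (6.53 to 14.9) and 9.73 points (5.89 to 13.6). These pairs were picked as the extremes, so their intervals do not allow for the choice.

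The X chromosome had fewer called promoters than the autosomes of the same array. On X, 208 of 818 regions (25.4%, 22.6 to 28.5) were called, against 3269 of 9885 autosomal regions (33.1%, 32.1 to 34.0). The difference was −7.64 points (−10.8 to −4.52). With the decile of input signal matched, the autosomal shares gave 226 ± 12.5 expected calls on X (counting SD), and the 208 observed lay within 2 SDs of that. The sex of the cells is not given in the sources used here.

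**Figure D4:**
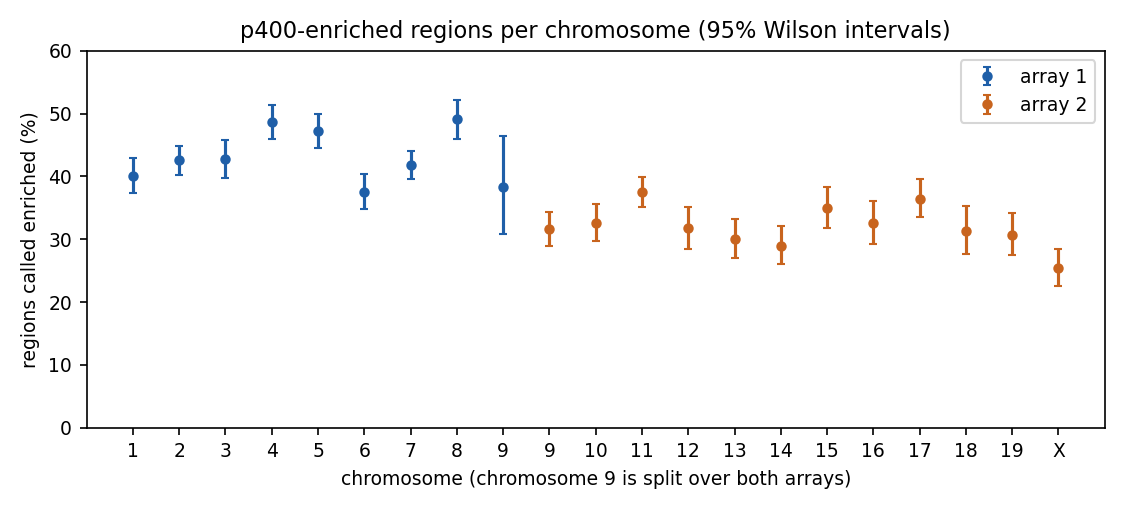
Percent of promoter regions called enriched in the p400 ChIP (vertical axis) per chromosome (horizontal axis), with 95% Wilson intervals, for array 1 (blue) and array 2 (orange). Among the chromosomes plotted, those with at least 100 regions on an array, X was lowest, at 25.4%, and chromosome 8 highest, at 49.1%, though on different arrays.

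Calls were not spread evenly along chromosomes. The longest stretch without a call was on chromosome 2 between 84933974 and 90202882 bp, where 226 successive regions over 5.27 Mb had a median peak of −0.03 and a highest peak of 0.75. Of the other regions of chromosome 2, 48.7% were called. In the stretch 98.2% of regions were exactly 4000 bp, the class called in 24.5% of cases on array 1, against 43.9% of the others. The median input signal of the stretch was 1245 against 1782 in the others. With centring on the random control probes, which called 80.6% of the regions of array 1, the longest such stretch there held 22 regions. Under each of the other alternatives for which it was counted, the longest stretch on array 1 held 190 to 227 regions. Further long stretches were 99 regions on chromosome 7 between 102358189 and 104067276 bp and 102 regions on chromosome 9 between 37418099 and 39938437 bp. With the authors' processed values the longest on array 2 held 60 regions.

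**Figure D5:**
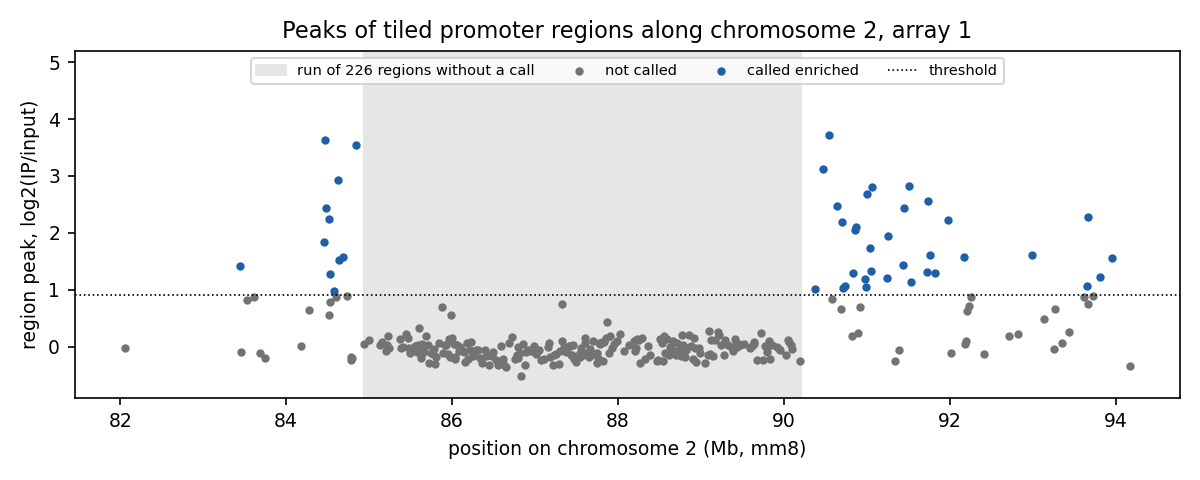
Peak log2(IP/input) of each tiled promoter region (vertical axis) against its position on chromosome 2 in Mb on mm8 (horizontal axis), array 1. Blue points were called and grey points were not, the dotted line is the threshold of 0.90, and the shaded stretch of 226 regions has a highest peak of 0.75.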

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

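Centring on the random control probes, removal of block medians over the array surface, regions with no other within 5000 bp, X against chromosomes 10 to 19 alone, the classes of tiled length, both contrasts within regions of 5500 to 6500 bp and the pairs of chromosomes and their matching by input signal were chosen after seeing the data. The gene list and CpG alternatives were not run, since regions could not be matched to genes or sequence of mm8. Signal over background of 2.02 to 3.21 limits what dim probes can show, and the effect of base composition was not tested. No paired analysis was possible because each array held 1 hybridisation. Causes were not tested for the changes below.

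Apart from centring on random probes, the number of regions called ranged from 3646 to 4804 on array 1 and from 2811 to 4601 on array 2. With that centring it was 8698 and 2580. Of the main calls of array 1, loess kept 77.8%, normexp 82.8% and the authors' values 95.2%. On array 2 each of these kept at least 99.8%. The deficit on X stayed between −10.4 and −5.50 points over 13 alternatives. Of 192 recomputed peaks of the 16 named regions, 147 stayed within a 95% interval from the SD of their 5 window probes. The others were higher in 19 cases and lower in 26, and all ran from 3.93 to 6.55. Those 5 probes are correlated and their window was picked as the highest, so these counts do not measure sampling error. The share called in regions up to 100 bp over 4000 bp stayed above that at exactly 4000 bp. The difference was 27.4 points on array 1 with loess and 17.6 with random-probe centring. On array 2 it was 27.2 with normexp, 26.9 with loess, 29.3 with the authors' values and 19.4 with random-probe centring.

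The dip in the middle of 5500 to 6500 bp regions on array 1 was −0.011 with normexp, turned in sign, 0.078 with loess and 0.29 with bins of 100 bp. The ratio near the middle over the edges was 1.03 on array 1 and 0.86 on array 2 with normexp. Chromosome 8 minus 6 was 0.12 with loess, and chromosome 11 minus 14 was 0.15 with normexp and 0.13 with the authors' values. Neighbouring probes on array 1 correlated at 0.716 with normexp, 0.763 with loess, 0.779 without block medians, 0.795 without dim and 0.772 without saturated probes. On array 2 they did so at 0.728, 0.771, 0.766 and 0.784 for the first 4 of these and 0.770 with the authors' values. Shared random probes correlated at 0.0954 with normexp, 0.20 with loess and 0.20 with the authors' values.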

Other observations

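The tests of the number of windows and of dim probes as the whole cause were chosen after related values had been seen, as was the requirement that the receptor relation hold without chromosomes 2 and 10, and the patterns below were themselves noticed in these data.

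The p400 ChIP peaks of promoters close together along the chromosome were weakly correlated. Across pairs of neighbouring regions, which are not independent replicates, the peaks of regions less than 10 kb apart correlated with r = 0.365 on array 1 and 0.295 on array 2. The values were 0.235 and 0.191 at 30 to 100 kb and 0.0301 and 0.0663 beyond 300 kb. Regions whose nearest neighbour was beyond 300 kb were called in 32.2% of 270 cases on array 1 (26.9 to 38.0) and 15.2% of 309 on array 2 (11.6 to 19.6). Those with a neighbour within 10 kb were called in 45.0% of 1937 (42.8 to 47.2) and 35.3% of 1916 (33.2 to 37.4).

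The longest rows of called promoters held 16 regions each, on chromosome 3 between 89175799 and 89439166 bp and on chromosome 7 between 126547529 and 126836818 bp. On array 2 the longest held 11, on chromosome 11 between 51424961 and 51848521 bp. A row of 14 on chromosome 2 between 174784188 and 176503713 bp stood apart by its input signal, a median of 7489 against 1713 in the other regions of the chromosome (percentile 99.6), and its peaks had a median of 2.32 and a highest value of 2.56. Of 49 regions on unplaced Y sequence, whose median input signal was 14553, 0 were called, which allows a share of up to 6.12% by 3 counts of 49 (95% Wilson upper limit 7.27%), and their median peak was −0.61. These limits take the regions as independent, while the regions form 1 stretch with input far above the array's median of 1119. They therefore say little about p400 on Y. A stretch of 58 regions without a call on chromosome 12 between 113707297 and 116445377 bp had an input signal at percentile 61.1 of its chromosome and 37.9% of its regions were exactly 4000 bp, against 47.3% of the others.

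The stretch of 226 uncalled regions on chromosome 2 was set against 1000 shuffles of the chromosome's calls. The longest stretch in these held 29, so calls in random order are argued against. Probes shared between gene copies were predicted to give a high input signal, and the percentile was 3.94, so that prediction was not met. The effect of base composition on input signal was not tested, so sharing among probes dim for that reason is not excluded. That percentile leaves dim probes open as part of the cause, but 1000 draws of calls over array 1, independent given the classes of input signal and tiled length, gave a longest stretch of 73 (median 26), which argues against them as the whole cause. Rows of olfactory and vomeronasal receptor genes were compared as 1 relation across 20 chromosomes, longest row against longest uncalled stretch, with rho = 0.505 (permutation p = 0.0248) and r = 0.884 (permutation p = 0.00049). Without chromosomes 2 and 10, which hold the longest receptor rows, the values were rho = 0.329 (permutation p = 0.180) and r = 0.570 (permutation p = 0.0124). The rank relation was thus not resolved without those chromosomes, which does not show that it rests on them. It had exceptions, such as chromosome 12 with a longest uncalled stretch of 58 regions and 0 receptor genes. The number of genes per chromosome was not adjusted for. Within arrays, over few chromosomes, rho was 0.452 on array 1 (exact permutation p = 0.267, n = 8) and 0.356 on array 2 (permutation p = 0.282, n = 11). A hypothesis is that receptor gene clusters may make up the stretch, but how much receptor content and dimness each contribute cannot be told apart here, because the stretch is dim and its regions are not named.

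Regions up to 100 bp longer than 4000 bp were called more often than those of exactly 4000 bp, by 29.6 and 24.4 points. They had fewer windows on average, with differences of −0.737 (SE 0.144) on array 1 and −0.996 (SE 0.145) on array 2, and with the decile of input signal matched the difference in calls was 28.3 and 23.4 points, which argues against both as the cause. A candidate explanation left open is that promoters with several annotated starts belong to genes with more transcript evidence, and so to genes active in more tissues. It was not tested, since the regions were not tied to genes, and base composition was not tested either.

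The X chromosome held 208 called regions where the autosomes of array 2, matched by decile of input signal, predicted 226 ± 12.5 (counting SD). The observed number lay within 2 of these SDs. The median input signal of X was 836, but input signal depends on the DNA copies of a chromosome as well as on its probes. Since the sex of the cells is not given, the match cannot show that dim probes cause the deficit. Tiled length alone predicted 263 ± 12.5, so it is not the whole cause. Leaving out stretches of at least 20 uncalled regions left a difference of −7.47 points (SE 1.76), which decides nothing, since it removes regions for not being called. No biological explanation was tested, and a deficit on X beyond the match by input signal was not detected here.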
